A study of Caenorhabditis elegans with 3 samples.

How the data were processed

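Each of the 3 samples is a two-colour array of Caenorhabditis elegans, with mRNA of a mixed wild-type reference in channel 1 and mRNA of 1 prep of early young adult hermaphrodites in channel 2, per the labels. Prep numbers were taken from the labels as replicate numbers 1 to 3, and all arrays form 1 group. The deposited values are 1 log2 ratio per probe and array. The base was read from the values: 2 raised to the deposited value was a whole multiple of 0.001, within 0.01 of a step, for 100.0% of the ratios under 1, against 3.12% with base e, 1.46% with base 10 and 3.18% for the inverse ratio. The dyes, the background correction, the normalization and the tools behind the deposited ratios are not given in the sources used here. The column medians were 0.01, 0.01 and 0.02 and the SDs over probes 0.69, 0.77 and 0.73 for preps 1, 2 and 3. The scale is thus log2 and the centring close to 0, while the normalization method and the dye orientation stay unknown. With no known dye swap, a gene-specific dye effect cannot be separated from a difference between worms and reference.

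The ratios were used as deposited, since no column median was farther from 0 than 0.1. Probes needed a value on all 3 arrays, which kept 19664 of 20000 and left out 336. No filter on dim spots was possible from the ratios. A table of the platform's annotation listed 15853 of the probes, 15655 with 1 gene symbol and 198 with several, and 4147 probes were not listed and stay unnamed. Of the single symbols, 15569 were matched in a table of WBcel235 genes, 0 symbols needed an update, and 86 had no match. Only names and chromosomes were taken from that table, and no coordinates, since the array has no stated build. A gene with several probes (414 genes) was given the mean of its probes on each array.

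The test was limma's one-sample test of the mean log2 ratio against 0 (lmFit on an intercept, eBayes), two-sided, with Benjamini-Hochberg adjustment at 0.05 over the probes for the total counts and over the 15078 genes for named genes, lists and chromosomes. The prior had 6.99 degrees of freedom and a SD of 0.25. The reference is common to the arrays and its own spread is not in the test. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 19 lists. camera with an estimated correlation, which rests on the residuals of 3 arrays, and fry were run beside it. fry's p tests whether a list moves one way on balance and its mixed p whether its genes change in either direction, and neither sets the list against other genes. With the preset correlation 12 lists passed. With an estimated correlation 0 passed, 0 at an unadjusted p of 0.05, and the smallest adjusted p was 0.340. By fry 12 passed. X-linked genes were compared with autosomal genes by a two-sided Fisher's exact test among genes with a chromosome, separately above and below the reference.

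The lists, the tests and the rule for named genes were fixed before the data were examined. Named were the 12 highest and 12 lowest genes by mean log2 ratio among those past the threshold with the same sign on all arrays and 1 current symbol, and the 2 highest and 2 lowest measured members of each list, 90 genes in all. Other genes named in the text were chosen after their values were seen, such as nhr-23 among the moulting genes, which was at 0.49 ± 0.09 (SD, n = 3). The lists hold yolk proteins, major sperm proteins, other sperm genes, oocyte and eggshell genes, meiotic genes, P granule and germline RNA genes, cell cycle genes, embryonic transcription factors, cuticle collagens, adult cuticle collagens, moulting genes, muscle, neurons, intestine, male-specific neurons, somatic gonad and vulva, ribosomal proteins, histones, and heat shock and stress genes.

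The steps were tested on simulated data with the measured spread, in which 200 of 19664 probes were changed. The test called 26% of those changed by 0.5 on the log2 scale, 98% of those changed by 1 and 100% of those changed by 2 or 3, with 13 unchanged probes called. In a further simulation the 8025 probes that the test had called were changed by their measured means and all others by 0. Of these, 94.3% were called, and 3.59% of the calls were unchanged probes. Since the changed probes were picked by the same test, that 94.3% is high by construction and does not measure power. Of unshifted lists, 2.5% had a camera p under 0.05. The simulated noise was drawn independently for each probe and the lists at random. These rates therefore do not cover genes that vary together or a drift along the probe list.

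The alternatives were centred, scale and quantile normalized arrays, probes on at least 2 arrays, a size limit of 1, robust eBayes, no moderation, a 1.2-fold margin, genes in place of probes, the sign turned, the X comparison without major sperm protein and histone genes, and each prep left out. Centring of blocks of neighbouring probes, removal of each array's own trend along the probe list, and the X comparison within blocks (Mantel-Haenszel) were added after a drift along the probe list was seen. The 32 blocks of equal size were inferred from the order of the probes and the ratios, not from a stated layout. Probes of a chromosome lie mostly together in the list, so centring blocks also takes out part of any difference between chromosomes. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.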

Results

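RNA from young adult hermaphrodites of the nematode Caenorhabditis elegans, taken at an early point of young adulthood, was measured on 3 two-colour DNA microarrays. Each array carried 1 prep of the worms in one channel and a mixed reference of wild-type mRNA in the other, so each value is a log2 ratio of the worms to that reference. The 3 preps form 1 group. Of 20000 probes, 19914 had a value for prep 1, 19829 for prep 2 and 19742 for prep 3, and 19664 had a value on all arrays. The number of arrays limits the precision, and spot intensities were not analysed here. Whether the preps came from separate cultures is not given in the sources used here, so the p-values measure only the spread between these preps, which may be technical.

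The sign of the ratios is likely worms over reference. This rests on the labels, which put the reference in channel 1 and the worms in channel 2, and on the adult cuticle collagen genes col-19, col-7 and col-62, whose mean log2 ratio was 2.60 ± 0.50 (SD of the 3 prep means, n = 3). The dyes are not given in the sources used here, and with the sign turned every direction below would be reversed. All values below are mean log2 ratios ± SD over the 3 preps (n = 3), with adjusted p from limma.

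The comparison of the worms with the mixed reference asks which genes were higher or lower in early young adults than in the mixed pool. Of the 19 fixed lists of genes, 12 passed camera at its preset correlation, with the sperm, oocyte, meiosis and P granule lists above the reference and the neuronal and moulting lists below it. With an estimated correlation 0 lists passed (smallest adjusted p = 0.340). Of 152 cuticle collagen genes, 55 were above the reference and 50 below. Of the 15078 genes tested the highest was irg-5, an infection response gene on chromosome V, at 4.12 ± 1.26 (adjusted p = 2.73e-05), though 3 probes without a listed gene were higher. The lowest was acs-2, an acyl-CoA synthetase gene on chromosome V, at −4.55 ± 0.77, a ratio 23.5-fold below the reference (adjusted p = 2.29e-06). Its rank rests on prep 2, at −5.44, with preps 1 and 3 at −4.13 and −4.08. In preps 1 and 3 the gene hsp-12.6 was lower, at −4.32 and −4.41.

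Among the 12 highest genes, 2 encode cuticle collagens. col-139 was at 3.49 ± 0.49, which is 11.2-fold above the reference, and col-129 was at 3.23 ± 0.28. The acyl-CoA dehydrogenase gene acdh-1 was at 3.45 ± 0.18. The UDP-glucuronosyltransferase genes ugt-22 and ugt-63 were at 3.36 ± 0.48 and 3.18 ± 0.13. pud-2.1 was at 3.41 ± 1.28, with prep 3 at 1.93 and preps 1 and 2 at 4.23 and 4.07. irg-5 showed the same split, with prep 3 at 2.67 against 4.71 and 4.97. The major sperm protein genes msp-33, msp-64 and msp-56 were at 3.23 ± 0.37, 3.06 ± 0.32 and 3.02 ± 0.23. Y38E10A.14 was at 3.13 ± 0.13, and srb-13, a member of a chemoreceptor family, at 3.00 ± 0.29. The adjusted p of these 12 genes ran from 1.04e-06 for acdh-1 to 8.77e-05 for pud-2.1.

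Among the 12 lowest genes, the small heat shock protein gene hsp-12.6 was at −4.45 ± 0.15, 21.8-fold below the reference, and the C-type lectin gene clec-60 was at −4.45 ± 0.45. The alcohol dehydrogenase gene adh-1 was at −4.38 ± 0.30 and F45D3.4 at −4.35 ± 0.32. far-7, a fatty acid and retinol binding protein gene, was at −3.87 ± 0.19, and the fatty acid desaturase gene fat-3 at −3.80 ± 0.10. cup-16 was at −4.04 ± 0.06, scl-2 at −3.97 ± 0.68 and F15E6.3 at −3.65 ± 0.61. The collagen genes col-36 and col-158 were at −3.96 ± 1.11 and −3.73 ± 0.75. The adjusted p of these 12 genes ran from 6e-07, for hsp-12.6 among others, to 1.84e-05 for col-36.

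**Figure D1:**
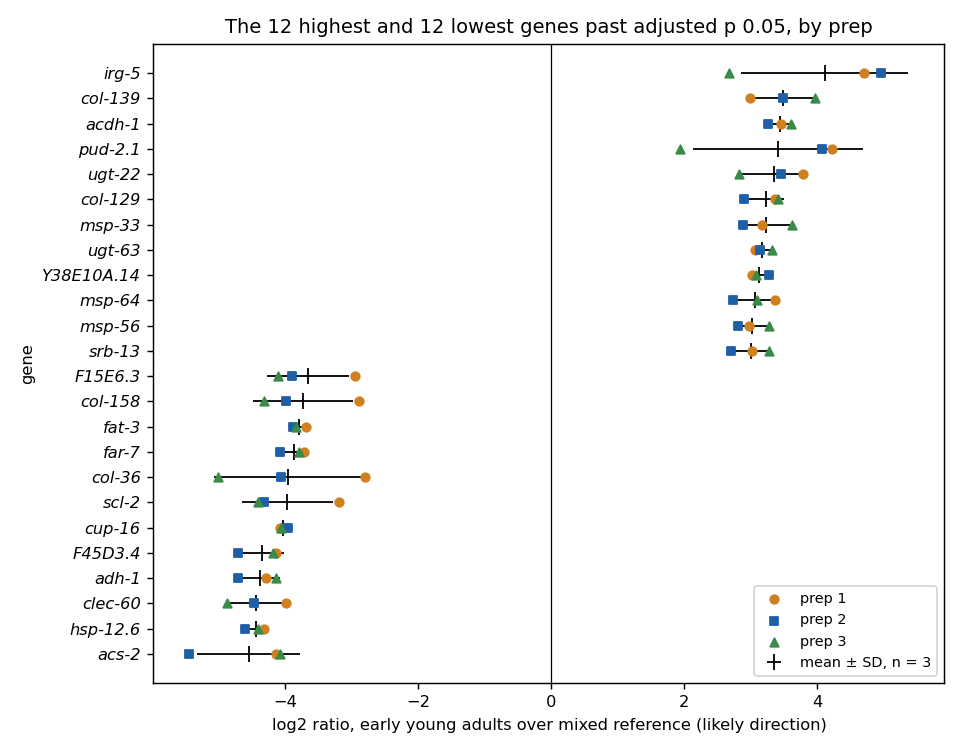
Log2 ratio of early young adults over the mixed reference (likely direction; x axis, no other unit) for the 12 highest and 12 lowest genes past adjusted p 0.05 (y axis), with 1 symbol per prep and a black bar for the mean ± SD, n = 3. irg-5 and pud-2.1 had prep 3 apart at 2.67 and 1.93, while cup-16 had a SD of 0.06.

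Sperm genes were above the reference as a group. Of 30 major sperm protein genes, 29 were above it and 1 did not pass (29 adjusted over the list alone), with a mean of 2.35 (camera adjusted p = 8.66e-22; adjusted p = 0.340 with an estimated correlation). msp-33 and msp-64 were the highest, msp-49 was at 1.38 ± 0.18, and msp-38 at −0.03 ± 0.06 did not pass (adjusted p = 0.873). These genes are near-identical copies that may share signal on an array, so the value of any 1 copy is uncertain. The count of 29 and the camera p at the preset correlation may likewise count a shared signal many times. Of 23 other sperm genes, 15 were above, 1 was below and 7 did not pass (16 above and 1 below adjusted over the list alone), with a mean of 0.86 (camera adjusted p = 3.52e-06; adjusted p = 0.374 with an estimated correlation). ssp-16 was at 2.87 ± 0.50 and ssp-19 at 2.08 ± 0.18. The sperm activation gene spe-27 was below the reference at −1.33 ± 0.22 (adjusted p = 8.19e-05), and fog-3 at −0.10 ± 0.34 did not pass.

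Oocyte and germline RNA genes were also above the reference. Of 32 oocyte and eggshell genes, 26 were above, 1 was below and 5 did not pass (26 above and 1 below adjusted over the list alone), with a mean of 0.87 (camera adjusted p = 6.52e-09; adjusted p = 0.384 with an estimated correlation). The RNA-binding protein genes puf-7 and puf-6 were at 2.02 ± 0.32 and 1.94 ± 0.37. The caveolin gene cav-1 was below at −2.04 ± 0.28 (adjusted p = 9.77e-06), and egg-1 at −0.27 ± 0.26 did not pass. Of 31 P granule and germline RNA genes, 27 were above and 4 did not pass (28 above adjusted over the list alone), with a mean of 1.08 (camera adjusted p = 1.38e-11; adjusted p = 0.340 with an estimated correlation). The helicase genes glh-1 and glh-2 were at 2.52 ± 0.64 and 2.203 ± 0.29, while ife-3 at 0.05 ± 0.10 and gld-4 at −0.11 ± 0.15 did not pass. Yolk protein genes gave no group shift: of 3 vitellogenin genes 1 was above and 2 did not pass (1 adjusted over the list alone), with a mean of 0.33 (camera adjusted p = 0.377). vit-2 was at 0.68 ± 0.68 (adjusted p = 0.0316), and its call was lost without prep 1 (0.42, adjusted p = 0.114) and without prep 2 (0.56, adjusted p = 0.0561), and its value was 1.07 without prep 3. vit-6 at 0.25 ± 0.20 and vit-5 at 0.05 ± 0.51 did not pass, although vit-6 passed without prep 1 (0.35, adjusted p = 0.0421).

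The lists of meiosis and of the cell cycle were above the reference too. Of 29 genes of the meiotic chromosome axis and recombination, 25 were above and 4 did not pass (26 above adjusted over the list alone), with a mean of 0.69 (camera adjusted p = 1.57e-08; adjusted p = 0.438 with an estimated correlation). The cohesin genes rec-8 and him-1 were at 1.25 ± 0.48 and 1.16 ± 0.18. him-8 at 0.20 ± 0.11 and him-5 at −0.20 ± 0.23 did not pass. Of 38 cell cycle and DNA replication genes, 31 were above and 7 did not pass (31 adjusted over the list alone), with a mean of 0.75 (camera adjusted p = 2.90e-10; adjusted p = 0.340 with an estimated correlation). The centromere protein gene hcp-4 was at 1.52 ± 0.15 and the phosphatase gene cdc-25.1 at 1.40 ± 0.35, while cdk-2 at −0.17 ± 0.25 and mcm-3 at −0.17 ± 0.36 did not pass.

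Genes of the neuronal list were below the reference. Of 109 genes, 76 were below, 1 was above and 32 did not pass (79 below and 1 above adjusted over the list alone), with a mean of −1.06 (camera adjusted p = 2.59e-18; adjusted p = 0.340 with an estimated correlation). Of the 109, 74 were taken by the name stems flp and nlp alone, without a check that each is neuronal. The median of these was −1.225, against −0.4395 for the 35 others. The neuropeptide genes flp-1 and nlp-80 were at −3.31 ± 0.13 and −3.06 ± 0.23. nlp-4 was above at 0.60 ± 0.11 (adjusted p = 0.00482), a call that ended under a test against a 1.2-fold margin (adjusted p = 0.0552). cat-2, which encodes tyrosine hydroxylase, was at 0.29 ± 0.08 and did not pass. Genes of male-specific neurons, listed as a check for the other sex, gave no group shift. Of 11 genes 1 was below and 10 did not pass (1 below adjusted over the list alone), with a mean of 0.01 (camera adjusted p = 0.829). The sex makeup of the reference is not given in the sources used here. A ratio near 0 therefore cannot show whether male RNA was present or absent in the worms. cwp-4 was at −0.73 ± 0.25 (adjusted p = 0.00266), cwp-2 at −0.13 ± 0.18, cil-7 at 0.16 ± 0.27 and lov-1 at 0.37 ± 0.23 (adjusted p = 0.0599), the last of which passed without prep 1 (0.47, adjusted p = 0.0144).

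Moulting genes were below the reference, and collagen genes lay on both sides. Of 28 moulting genes, 19 were below, 3 were above and 6 did not pass (20 below and 4 above adjusted over the list alone), with a mean of −0.85 (camera adjusted p = 7.24e-06; adjusted p = 0.360 with an estimated correlation). ptr-4 was at −2.65 ± 0.30 and noah-1, which encodes a protein of the apical matrix, at −2.32 ± 0.38. Above the reference were nhr-23 and also tmem-131 at 0.76 ± 0.23 and the protease gene bli-4 at 0.56 ± 0.31, whose call ended once blocks of neighbouring probes were centred (0.35 ± 0.19, adjusted p = 0.0571), as the value fell. Of 152 cuticle collagen genes, 55 were above, 50 were below and 47 did not pass (57 above and 52 below adjusted over the list alone). Of these, 37 were above and 34 below by at least 1. The mean of the list was 0.11 and its median 0.00 (camera adjusted p = 0.377), the mean was −0.03 without prep 1, and without prep 2 it was 0.19 with a camera adjusted p = 0.0367. fry's test for change in either direction gave an adjusted p = 0.00282. Every list but the yolk proteins (fry mixed adjusted p = 0.389) passed that test, so it does not set the collagens apart. All 3 adult cuticle collagen genes, which are also in the larger list, were above (3 adjusted over the list alone; camera adjusted p = 0.00101; adjusted p = 0.374 with an estimated correlation), with col-62 at 2.69 ± 0.84, col-19 at 2.60 ± 0.06 and col-7 at 2.51 ± 0.63. The sign of the ratios was set partly by these 3 genes, so their direction is no separate result. Collagen genes resemble one another in sequence, so single values may hold signal from relatives.

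**Figure D2:**
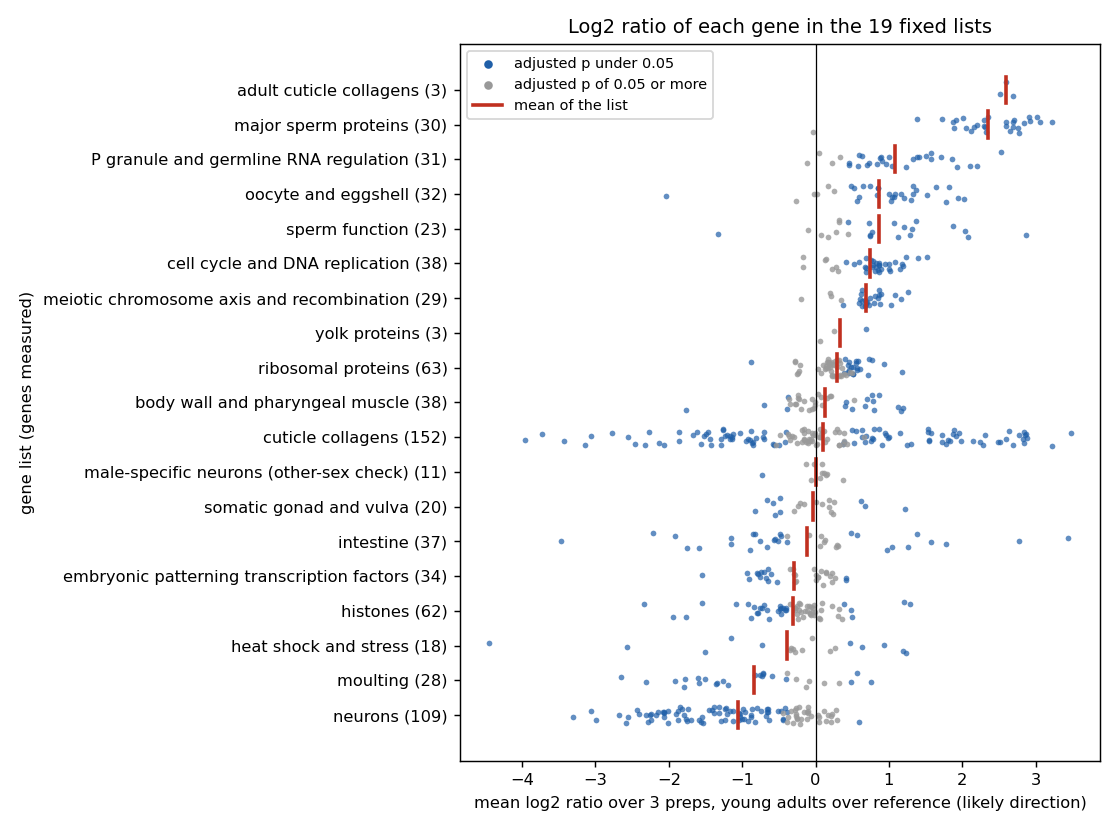
Mean log2 ratio over the 3 preps (x axis, likely direction) of each gene in the 19 fixed lists (y axis, number of genes measured in brackets). Each point is 1 gene, blue past adjusted p 0.05 and grey otherwise, points are spread vertically at random, and the red bar is the mean of the list. Major sperm protein genes centre on 2.35 and neuronal genes on −1.06, while the 152 cuticle collagen genes span both sides.

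Body wall and pharyngeal muscle, intestine and somatic gonad gave no group shift, with members on both sides. Of 38 muscle genes, 12 were above, 4 were below and 22 did not pass (12 and 4 adjusted over the list alone), with a mean of 0.13 (camera adjusted p = 0.357). The troponin T genes mup-2 and tnt-2 were at 1.197 ± 0.40 and 1.17 ± 0.32, the troponin C gene tnc-2 at −1.76 ± 0.25 and unc-97 at −0.70 ± 0.26. Of 37 intestinal genes, 10 were above, 18 were below and 9 did not pass (10 and 18 adjusted over the list alone). Their median was −0.39 and their mean −0.11 (camera adjusted p = 0.377), or −0.05 without prep 3 (adjusted p = 0.718). Besides acdh-1, the cysteine protease gene cpr-5 was at 2.77 ± 0.23, against −3.47 ± 0.46 for the metallothionein gene mtl-1 and −2.21 ± 0.27 for the ferritin gene ftn-1. Of 20 somatic gonad and vulva genes, 3 were above, 6 were below and 11 did not pass (3 and 6 adjusted over the list alone), with a mean of −0.04 (camera adjusted p = 0.808), or −0.02 without prep 2 (adjusted p = 0.977). The basement membrane collagen gene emb-9 was at 1.22 ± 0.22 and the filamin gene fln-1 at 0.67 ± 0.12, while spv-1 was at −0.82 ± 0.54 and the Hox gene egl-5 at −0.67 ± 0.36. The call of egl-5 was lost without prep 2 (−0.54, adjusted p = 0.0667).

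Smaller shifts were seen for embryonic transcription factors, ribosomal proteins and histones. Of 34 embryonic patterning genes, 13 were below, 2 were above and 19 did not pass (13 below and 2 above adjusted over the list alone), with a mean of −0.29 (camera adjusted p = 0.0233; adjusted p = 0.377 with an estimated correlation; adjusted p = 0.0848 without prep 2). sdz-24 was at −1.55 ± 0.20 and the homeobox gene ceh-27 at −0.94 ± 0.29. pal-1 was at 0.42 ± 0.08 and tlf-1 at 0.41 ± 0.15. The call of pal-1 was lost without prep 2 (0.46, adjusted p = 0.131) and without prep 3 (0.38, adjusted p = 0.172), and so was that of tlf-1 (0.35, adjusted p = 0.283, and 0.49, adjusted p = 0.0729). With blocks of neighbouring probes centred both values fell and both calls ended, with pal-1 at 0.31 ± 0.08 (adjusted p = 0.0682) and tlf-1 at 0.21 ± 0.20 (adjusted p = 0.248). Such centring may also remove the level of a chromosome, whose median was 0.15 on III, with pal-1, and 0.17 on I, with tlf-1. Of 63 ribosomal protein genes, 22 were above, 1 was below and 40 did not pass (21 above and 1 below adjusted over the list alone), with a mean of 0.30 (camera adjusted p = 1.63e-04; adjusted p = 0.574 with an estimated correlation; fry adjusted p = 0.0930). rpl-11.1 was at 1.19 ± 0.16 and rpl-23A.2 at 0.94 ± 0.04, while its paralog rpl-23A.1 was at −0.88 ± 0.11. rpl-38 at −0.28 ± 0.23 did not pass, except without prep 1 (−0.36, adjusted p = 0.0453). Of 62 histone genes, 24 were below, 5 were above and 33 did not pass (24 and 5 adjusted over the list alone), with a mean of −0.31 (camera adjusted p = 0.00375; adjusted p = 0.482 with an estimated correlation). Linker histone genes took both ends of this list, with hil-5 at 1.29 ± 0.27 and hil-4 at 1.203 ± 0.18 against hil-3 at −2.34 ± 0.39 and his-24 at −1.94 ± 0.60. Core histone genes are near-identical copies and uncertain one by one.

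Of 18 heat shock and stress genes, 5 were above, 5 were below and 8 did not pass (5 above and 6 below adjusted over the list alone). The mean was −0.39 (camera adjusted p = 0.389, fry adjusted p = 0.0303). The chaperone genes hsp-4 and hsp-1 were at 1.23 ± 0.13 and 1.196 ± 0.40, whereas the small heat shock protein genes hsp-12.6 and hsp-12.3 were at −4.45 ± 0.15 and −2.57 ± 0.32.

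Over all probes, 8025 of 19664 (40.8%) passed the limma test at a Benjamini-Hochberg adjusted p of 0.05, with 4063 above and 3962 below the reference. At an unadjusted p of 0.05 the count was 9534. Of the 8025, 1071 were above and 1248 below by at least 1, and 1369 had no listed gene. By gene, 6629 of 15078 passed, with 3278 above and 3351 below. The sign was the same on all arrays for 12733 probes (64.8%), where independent signs would give 25%. The arrays share a reference and have no known dye swap, so equal signs can also arise without a difference in the worms. The count rests on the variance shared across probes: without that moderation 1 probe passed, and 4777 passed when tested against a 1.2-fold margin.

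The chromosomes differed in how many of their genes stood above or below the reference. Of 2249 genes on the X chromosome, 146 (6.49%) were above, against 3120 of 12751 autosomal genes (24.5%), an odds ratio of 0.214 (95% interval 0.179 to 0.255, two-sided Fisher's exact p = 1.87e-99). Below the reference were 750 X-linked genes (33.3%) against 2592 autosomal genes (20.3%), an odds ratio of 1.96 (95% interval 1.78 to 2.16, two-sided Fisher's exact p = 1.66e-39). The median log2 ratio was 0.17 on chromosome I, 0.09 on II, 0.15 on III, 0.07 on IV, −0.08 on V and −0.22 on X. On X it was −0.31 for prep 1, −0.16 for prep 2 and −0.19 for prep 3. Named X-linked genes lay on both sides, with col-19 at 2.60 and mup-2 at 1.197 against ptr-4 at −2.65 and hil-3 at −2.34. The probes of X and V lie late in the probe list and those of I, II and III early, and ratios drifted along the list. Compared only within blocks of neighbouring probes, the odds ratio of X was 0.366 above (95% interval 0.305 to 0.440) and 1.65 below (95% interval 1.48 to 1.84). Within blocks X met mostly V and IV, so the change from 0.214 mixes position with the choice of autosomes. In the later part of the list 13.02% of genes on V, 24.75% on IV and 6.5% on X were above. Chromosome IV, which lies in both parts, had 29.36% above in the early part. Counting only genes at least 1 from the reference, without blocks, the odds ratio of X was 1.256 below (two-sided Fisher's exact p = 0.00717). Genes are not independent replicates, so these p-values describe this set of genes.

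**Figure D3:**
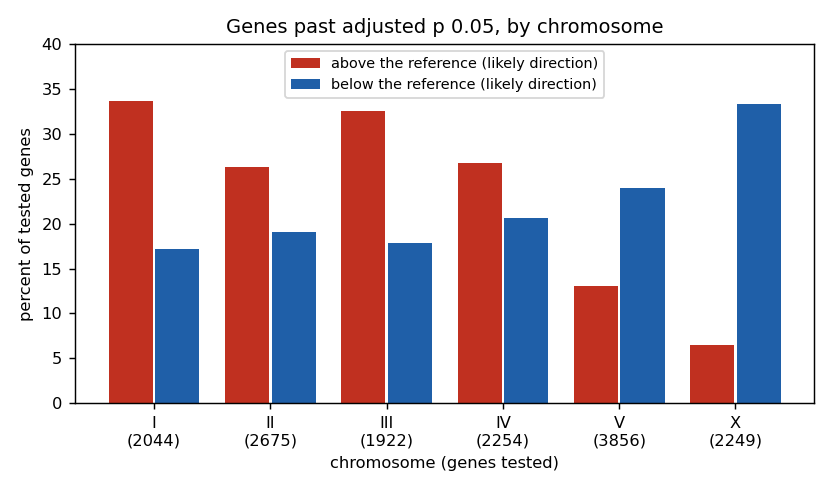
Percent of tested genes (y axis) past adjusted p 0.05 above the reference (red) and below it (blue) on each chromosome (x axis, genes tested in brackets), in the likely direction. Above the reference were 6.49% of X-linked genes and 33.7% of genes on chromosome I, and below it 33.3% and 17.2%.

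The preps were compared across probes to show the replicate error. The log2 ratios of preps 2 and 3 correlated at r = 0.909 (rho = 0.876), those of preps 1 and 2 at r = 0.803 (rho = 0.708) and those of preps 1 and 3 at r = 0.775 (rho = 0.689). The SD of the difference between preps was 0.32 for preps 2 and 3, 0.46 for preps 1 and 2, and 0.48 for preps 1 and 3, and the median SD per probe was 0.22. These correlations run over probes, which are not independent replicates. Among the lists, prep 1 stood highest above the mean of the other preps for cuticle collagens, by 0.40. It stood farthest below that mean for the adult cuticle collagens, at −0.46, and the sperm genes other than major sperm proteins, at −0.36. For the adult cuticle collagens it was prep 3 that lay apart, with list means of 2.295, 2.332 and 3.173 for preps 1, 2 and 3. Those sperm genes rose in steps, with list means of 0.63, 0.88 and 1.08.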

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

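The alternatives that address the position of probes in the list were chosen after the data were seen. Of the 8025 probes past the threshold, counts within 1.5 times were found with centred, scaled or quantile normalized arrays, probes on at least 2 arrays, robust eBayes, genes in place of probes and both corrections for position. Leaving out 1 prep gave 5790 to 9581 probes, the highest without prep 1. The size limit of 1 left 2319 probes (1071 above, 1248 below), and the 1.2-fold margin left 4777 (2382 above, 2395 below), both by construction. Without moderation of the variance 1 probe passed, 1 above and 0 below, in the unmoderated test with 2 residual degrees of freedom, although 6647 had an unadjusted p under 0.05 (3233 above, 3414 below). No gene then passed (smallest adjusted p = 0.0665), so the X comparison gave no value there.

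With the sign turned, the odds ratio of X became 1.96 above and 0.214 below the reference, by construction, and the probe counts, the values of all named genes and the list means exchange sign. Under the other alternatives it stayed under 1 above and over 1 below, where it was nearest 1 with the size limit (1.256) and then with blocks centred (1.379). With an estimated correlation 0 lists passed in camera in place of 12. fry passed 12, without the ribosomal proteins and with the heat shock genes. With probes on at least 2 arrays, where the list test ran on the statistics alone, cuticle collagens (adjusted p = 0.0223) and heat shock genes (adjusted p = 0.0452) passed too. Neither list gained a gene, since all 152 and 18 on the array were in the main run, and their means stayed at 0.11 and −0.39. Added list genes therefore do not account for the change. The changed form of the test was not told apart from the probes added outside these lists. Over their alternatives the adjusted p of these lists ran from 0.0223 to 0.978 and from 0.0303 to 0.610. The mean correlation of the preps was 0.829 over all probes and 0.950 over probes with a mean of at least 1 in size, as that limit picks large ratios.

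Of the 90 named genes, 74 had a call in the main test, and all of these lost it without moderation. The call was lost by 14 with the size limit, 6 with the margin, 3 with blocks centred and 1 with the arrays' own trends removed. Over the alternatives the adjusted p of vit-2 ran from 5.67e-04 to 0.348, of pal-1 from 0.0163 to 0.312, of tlf-1 from 0.0279 to 0.362, of bli-4 from 0.00879 to 0.189 and of egl-5 from 2.57e-04 to 0.187. The causes were not tested. Signal over background was not analysed here, so what dim spots limit is unknown.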

Other observations

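The gene classes in this part were scanned after the data were seen. The tests of neurons against muscle and of the noise expected for prep 1 were also added then. The X comparison below the reference was planned, but its use against ratios pulled towards 0 was chosen after the data were seen. Outside the fixed lists, 173 classes of genes with a shared name stem and at least 8 members were tested with camera at the preset correlation, and 42 passed a Benjamini-Hochberg adjusted p of 0.05, 17 above and 25 below the reference. None of those named here passed with an estimated correlation (adjusted p = 0.759). Above the reference stood the nucleoporin genes (npp), with 17 of 21 genes above and a mean of 0.85 (adjusted p = 2.39e-06), the proteasome regulatory subunit genes (rpn), with 12 of 13 and a mean of 0.81 (adjusted p = 1.02e-04), and the splicing factor genes (prp), with 9 of 11 and a mean of 0.64 (adjusted p = 0.00345). The translation initiation factor genes (eif) had 11 of 19 above with a mean of 0.48 (adjusted p = 0.00697). The highest npp gene was npp-9 at 1.86, the highest prp gene prp-39 at 1.32 and the highest rpn gene rpn-1 at 1.24.

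Below the reference stood the transthyretin-related genes (ttr), with 27 of 46 below, 2 above and a mean of −0.68 (adjusted p = 3.72e-06), and the nuclear hormone receptor genes (nhr), with 77 of 232 below, 2 above and a mean of −0.31 (adjusted p = 3.97e-04). The hedgehog-related genes wrt and grl had 6 of 10 and 10 of 23 below, with means of −0.93 and −0.75 (adjusted p = 0.00928 and 0.00630). Insulin-like genes (ins) had 11 of 21 below with a mean of −0.57 (adjusted p = 0.00630), and neuropeptide receptor genes (npr) 14 of 41 with a mean of −0.33 (adjusted p = 0.00688). Besides acs-2, the lipase gene fil-1 was at −3.20 ± 0.34 and icl-1, which encodes a glyoxylate cycle enzyme, at −2.65 ± 0.47 (SD, n = 3), while the lipase gene lipl-5 was at 1.94 ± 0.43. These 3 genes were chosen after their values were seen.

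Neuronal genes stood below the reference while muscle genes on balance did not. If germline RNA merely diluted all somatic RNA, both lists would shift alike, but their medians differed by −1.013 (neurons minus muscle, two-sided permutation p = 1.2e-04). That argues against dilution as the whole cause, though the difference restates the pattern and its p treats genes as independent. Neuropeptide genes as the whole cause are argued against by the 35 neuronal genes outside the flp and nlp classes, of which 19 were below and 0 above, with a median of −0.4395 against −1.225 for the 74 flp and nlp genes. In camera these 35 passed 0.05 with the preset correlation and did not with an estimated correlation (p = 0.15). A reference richer in neuronal RNA, such as one with many larvae, may give this pattern, but the makeup of the reference is not given in the sources used here and this was not tested.

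X-linked genes were rare among genes above the reference. Ratios of X probes pulled towards 0 would make them rare below it too, but the odds ratio there was 1.961 (95% interval 1.78 to 2.16). The fixed lists do not carry the pattern, since without their genes the odds ratio above was 0.2077 (0.172 to 0.250). Position in the probe list does not account for it whole, since within blocks, mostly against V and IV, the odds ratio was 0.3659 (0.305 to 0.440). Genes of the germline lists were rare on X, 1 of 145 against 2248 of 14855 other genes, an odds ratio of 0.03894 (95% interval 0.000983 to 0.221, two-sided Fisher's exact p = 2.62e-09). The hypothesis that X-linked genes may be scarce above the reference because germline genes are scarce on X stays open, as does a share for the position of the probes.

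Prep 1 stood apart from preps 2 and 3. Independent noise between spots as the whole cause is argued against by 402 genes with 2 probes. Their deviations in prep 1 from the other preps correlated at 0.3275 (95% interval 0.237 to 0.412). If the excess of prep 1 were independent between spots, 0.0933 was expected (difference 0.234, 95% bootstrap interval over genes 0.136 to 0.326). Prep 2 minus prep 3 gave 0.225. A correlation of this size leaves room for such noise as a part. A smooth trend along the probe list took 19.13% of the variance of the deviations of prep 1. For prep 2 minus prep 3 it took 5.26%, and with the probe order shuffled at most 0.673%. With each array's trend removed, prep 1 correlated with the mean of the others at 0.8431, against 0.808 before. The trend may thus be part of the difference and is not the whole. What else sets prep 1 apart, such as the worms or the handling of the RNA, was not tested.

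Turning the sign of single arrays gave 4 patterns of signs. Of these, 1 gave as many calls as the real one, which is the real pattern itself with 8025 probes, and the highest of the others gave 0. With 4 patterns no share under 0.05 can be reached.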
